A study of Mus musculus with 12 samples.

How the data were processed

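PolyA RNA of mouse primary hepatocytes, freshly isolated liver parenchymal cells in culture, was sequenced in 12 libraries. The labels cross 2 temperatures, 34 °C and 38 °C, with 2 additions. DMSO is the solvent control. Cycloheximide (CHX) stops translation elongation and, because nonsense-mediated decay (NMD) of mRNA needs translation, also stops that decay. Each of the 4 groups holds 3 libraries. Per the labels, cells were kept at a first temperature for 12 h and then shifted, DMSO or CHX was added 4 h later, and RNA was taken after 4 h with the addition. The labels leave open whether 34 °C and 38 °C name the temperature before or after the shift, so the comparisons are between the labelled groups. The protocol also mentions cells kept at 39 °C, a temperature that no library label carries. Mouse strain, sex and isolation day were not in the sources used here.

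The authors gave, per the file headers, 2 values for each gene in each library: TPM, a transcript abundance scaled to the same total in every library and rounded to 1 decimal, and read counts. The deposited read counts are fractional, so they are expected counts from an estimating quantifier, unscaled between libraries. The aligner, the quantifier, the genome build and the use of strand are not given in the sources used here. Each file lists 54532 Ensembl mouse genes, of which 54409 (99.77%) matched GENCODE vM21 by ID, which gave symbols, gene types, annotated exon overlaps and annotated NMD transcripts. Genomic positions are not printed, because the build behind the files is not given.

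Genes with a mean TPM of at least 1 over the 12 libraries were tested, which left 13114. Rounded expected counts were scaled by the TMM method and fitted in R 4.3.3 with edgeR 4.0.16 by quasi-likelihood, with 1 mean per group and all 12 libraries in the fit. The plan named limma on log2(TPM + 1), with edgeR as the test if the files held counts; they hold both, edgeR was used, and limma 3.58.1 on log2(TPM + 1) was run as an alternative. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 5 contrasts were 38 °C against 34 °C in DMSO, 38 °C against 34 °C in CHX, CHX against DMSO at 34 °C, CHX against DMSO at 38 °C, and the interaction, which is the difference between the CHX and DMSO temperature responses. Levels are printed as TPM, mean ± SD with n = 3. Fold changes come from the counts and log2 changes are ± SE. The fold and the TPM ratio of a gene can differ, because the authors' TPM also divides by an estimated transcript length. All p-values measure only the spread between these samples.

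Shared calls between 2 contrasts were set against the number expected from independent calls, per direction. The DMSO and CHX temperature contrasts share no library, and neither do the CHX contrasts at the 2 temperatures. Correlations between contrasts are across genes, which are not independent replicates.

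Of 38 gene lists, 35 had at least 3 tested genes and were tested with limma's camera, two-sided, with the correlation between genes estimated for each list and adjustment over the 35 lists of a contrast, 175 tests in all. The lists were cold-inducible RNA-binding, heat shock response, SR protein and Tra2, hnRNP and PTB, other RNA-binding and core splicing, splicing kinase, NMD factor, snoRNA host, ATF4 and integrated stress, ER chaperone, immediate early, NF-kB and chemokine, p53 target, circadian clock, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPAR alpha target, cytochrome P450, secreted plasma protein, acute phase, gluconeogenesis and urea cycle, hepatocyte transcription factor, NRF2 target, metallothionein and hypoxia, cytosolic ribosomal protein, ribosome biogenesis, proteasome, nuclear-encoded respiratory chain, mitochondrially encoded, replication-dependent histone, cell cycle and nuclear retained noncoding genes, with 6 lists of markers of other cells that a hepatocyte preparation can hold: Kupffer cell and macrophage, liver endothelial cell, stellate cell and fibroblast, cholangiocyte, lymphocyte and neutrophil, and red blood cell. The camera test with a preset correlation of 0.01 and the fry test, which asks only whether a list's genes move on balance one way, were run beside it. The count of members called was also made with p adjusted over the list alone.

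Lists, contrasts, filters, thresholds and the rule for named genes were fixed before the data were examined. The rule named, for each contrast, the 8 largest rises and the 8 largest falls on the log2(TPM + 1) scale among called genes with a mean TPM of at least 5 and groups that do not overlap, which 10% of genes show by chance with 3 against 3 libraries. For the interaction no overlap condition was used. It left out clone and predicted names, added up to 4 members of each list discussed, those with the smallest adjusted p, and always named 15 genes.

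Total counts ran from 24627186 to 39017400 per library. The test was checked on simulated counts with 200 changed genes per contrast: edgeR recovered 23.9 to 29.9% of true changes of 1.5-fold in the 4 pairwise contrasts, 62.7 to 71.6% of 2-fold changes and 90.9 to 97.0% of 4-fold changes, with 4 to 8 false calls. For the interaction it recovered 4.48%, 31.3% and 83.3%. Far more genes were called in the data than the 200 changed here, and fewer true changes make the adjusted threshold stricter. These shares therefore do not give the power of the real tests. Where a group held 3 counts or fewer of a gene, the fold is a ratio with its 95% counting interval, or, with 0 counts, a lower bound against a floor of 3 counts over the group. Intervals and floors cover counting error only. Reads of near-identical histone genes, of Hspa1a and Hspa1b, of pseudogenes and of overlapping genes are hard to assign: the second Ensembl entry of Ddit3, Hist2h3c1 and Snord22 lie within exons of another gene on the same strand, and parts of Ankrd37, Txnip, Hspa1a, Rgs16 and Jun lie over exons of the other strand. No library was a copy of another: chi-square per gene ran from 14.6 to 619 over all pairs of libraries.

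Alternatives tried were median-of-ratios and quantile scaling, no scaling beyond totals, other filters, pseudocounts of 0.1 and 5 on log2 TPM, no variance trend, array weights, the compared groups alone, a minimum log2 change of 1, DESeq2 1.42.0, a fit with replicate number as a term, leaving out each library, leaving out mitochondrially encoded genes, and the 6791 protein-coding genes with no annotated exon overlap. For gene lists and named genes, camera and limma on log2(TPM + 1) and on log2 scaled counts were also tried, to part the input from the pseudocount. Of these, the fits of log2(TPM + 1) and of log2 scaled counts, DESeq2, totals alone and the genes with no overlap were chosen after seeing the data, and so was the reading of the fit without 38 °C CHX replicate 3. No library was left out of the main tests.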

Results

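Gene expression was measured in 12 polyA RNA-seq libraries of cultured mouse hepatocytes: 3 labelled 34 °C with DMSO, 3 labelled 34 °C with CHX, 3 labelled 38 °C with DMSO and 3 labelled 38 °C with CHX. The values are for whole genes, so no exon or splice junction was counted. Total counts were 26388526, 37364884 and 37542396 for replicates 1, 2 and 3 of 34 °C DMSO, 37416446, 32717470 and 34633763 for 34 °C CHX, 33966273, 33121635 and 24627186 for 38 °C DMSO, and 35593905, 33474880 and 39017400 for 38 °C CHX. Alb, the serum albumin gene, stood at 32200 ± 1540 TPM in 34 °C DMSO and at 36800 ± 1340 TPM in 38 °C DMSO (mean ± SD, n = 3; every level given as a mean ± SD is over 3 libraries).

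The first principal component of the libraries, computed from log2 scaled counts, took 55.1% of the variance and parted CHX from DMSO. The DMSO libraries of both temperatures lay between -60.8 and -50.7 on it, those of 34 °C CHX between 28.2 and 36.6, and those of 38 °C CHX between 64.1 and 98.2. Replicate 3 of 38 °C CHX stood apart. Its correlations with its group mates on log2(TPM + 1) were 0.909 to 0.915, against at least 0.965 between the mates of the other groups. Over the 6791 protein-coding genes with no annotated exon overlap its correlations were 0.982 to 0.986.

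**Figure D1:**
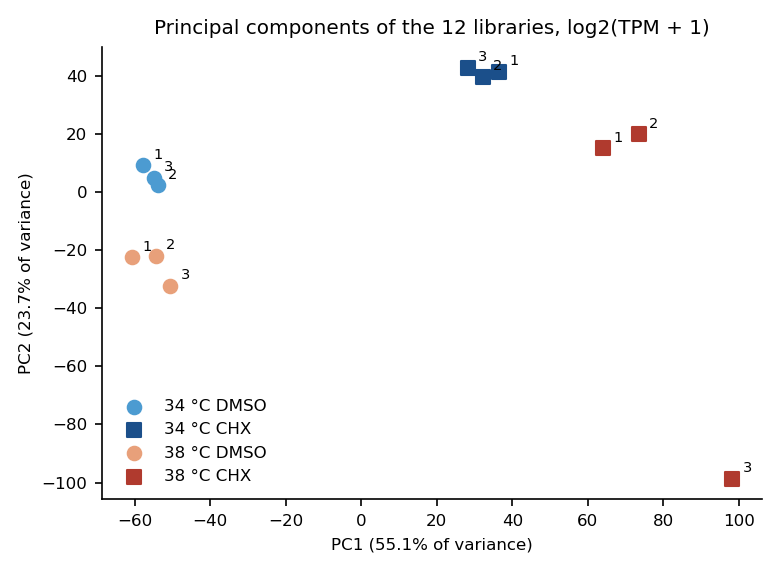
Each point is 1 of the 12 libraries on the first (55.1% of variance) and second (23.7%) principal components, coloured by group. The components were computed from log2 scaled counts, not from the log2(TPM + 1) named in the title of the plot. CHX and DMSO part on the first component, and replicate 3 of 38 °C CHX lies at 98.2 on the first and -98.6 on the second.

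In DMSO, 38 °C libraries were set against 34 °C libraries to ask how the hepatocyte transcriptome differs between the temperatures while translation runs. Heat shock response genes, which encode chaperones and their partners, were higher at 38 °C: 20 of 25 rose, 1 fell and 4 were not called, with a median log2 change of 0.62. Hsph1, a chaperone of the Hsp110 family, rose 2.88-fold, from 32.6 ± 3.06 to 93.6 ± 8.59 TPM (adjusted p = 1.1e-05). The cold-inducible RNA-binding pair moved the other way. Cirbp fell 5.13-fold, from 39.9 ± 5.45 to 9.93 ± 1.46 TPM (adjusted p = 3.3e-06), and Rbm3 fell 1.38-fold, from 174 ± 22.4 to 126 ± 27 TPM (adjusted p = 0.028). The call of Rbm3 was lost without replicate 2 or 3 of 34 °C DMSO or replicate 1 or 2 of 38 °C DMSO, and in limma fits of log2 TPM with a pseudocount of 0.1, 1 or 5, with adjusted p from 0.00817 to 0.121.

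The heat shock list was the 1 list of 35 whose shift passed the test in DMSO, with camera's adjusted p = 0.00538 with an estimated correlation. Camera on log2(TPM + 0.1) ended its call (adjusted p = 0.135), and so did log2(TPM + 1) (0.141), while on log2 scaled counts it stayed (0.0169). The call was thus lost on TPM at either pseudocount. The TPM fits also change the scaling, so the choice behind the loss was not singled out. The camera test of this list had an adjusted p from 0.00303 to 0.0186 under the alternatives on counts. Adjusted over the list alone, 21 rose and 1 fell; for every list whose count adjusted over the list alone is not given, that count was the same as the one over all genes. Stip1, which links the Hsp70 and Hsp90 chaperones, rose 2-fold, from 93 ± 6.33 to 194 ± 5.45 TPM. Fkbp4, a partner of Hsp90, rose 1.85-fold, from 153 ± 7.63 to 256 ± 9.03 TPM, and Hspa4l, of the Hsp110 family, rose 2.1-fold, from 12.5 ± 0.603 to 28.1 ± 6.39 TPM. The inducible Hsp70 genes were near the floor. Hspa1a rose 5.37-fold, from 0.367 ± 0.0577 to 1.87 ± 0.929 TPM (adjusted p = 0.0035) and Hspa1b rose 2.71-fold (adjusted p = 0.026). Hsp90aa1, the inducible Hsp90, rose 1.47-fold (adjusted p = 0.0076), a call lost in all 4 limma fits of log2 TPM tried for single genes (pseudocounts of 0.1, 1 and 5 and quantile scaling) and kept by limma on log2 scaled counts (adjusted p from 0.00262 to 0.315). Its log2 change was 0.22 on log2(TPM + 1), and its ratio of counts to TPM rose by log2 0.34 between the groups. The call of Hspa1a was lost on log2(TPM + 5) and kept on log2(TPM + 1) (0.000423 to 0.0651). The call of Hspa1b was lost without replicate 2 or 3 of 34 °C DMSO or replicate 1 of 38 °C DMSO, with adjusted p from 0.01 to 0.0867 over its alternatives.

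Over all 13114 genes, edgeR called 1382 higher and 1369 lower at 38 °C in DMSO, 2751 in all (21%). Of these, 198 rose and 334 fell by at least 2-fold. The balance turned in 6 of 28 alternatives, and the share higher ran from 37.2% to 61.8%. The lower genes numbered 755, 822 and 767 without replicates 1, 2 and 3 of 34 °C DMSO, and 691 without replicate 2 of 38 °C DMSO. The whole count was 1811 without that last library, and 3874 without replicate 3 of 38 °C CHX, which enters only the estimate of spread.

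Among the largest rises in DMSO, Ccl20, a chemokine, rose 16.4-fold, from 0.4 ± 0.1 to 7.27 ± 1.64 TPM (adjusted p = 0.00036). Ankrd37, a target of hypoxia-inducible factor, rose 8.93-fold, from 1.6 ± 0.2 to 13.6 ± 2.4 TPM, and Serpine1, the inhibitor of plasminogen activators, rose 4.62-fold, from 30.8 ± 6.46 to 142 ± 41 TPM. Banp, a nuclear DNA-binding protein, rose 7.86-fold, from 2.03 ± 0.153 to 11.2 ± 1.4 TPM. Cib3 rose 4.11-fold, Samd1 4.28-fold, the noncoding RNA Wincr1 4.65-fold and the pseudogene Rpl9-ps6 4.64-fold, the last with reads that are hard to part from those of its parent gene. Among the largest falls, Hamp, which encodes the iron hormone hepcidin, fell 11.4-fold, from 246 ± 36.6 to 22.3 ± 10.4 TPM (adjusted p = 0.00014). Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, fell 6.88-fold, from 613 ± 76.4 to 92.8 ± 2.26 TPM (adjusted p = 7.2e-05). Serpina7, the thyroxine-binding globulin, fell 3.39-fold, from 1110 ± 136 to 272 ± 59.1 TPM, and Ugt2b35, a glucuronosyltransferase, fell 4.28-fold, from 149 ± 28.1 to 36.3 ± 6.82 TPM. G6pc, the glucose-6-phosphatase that releases glucose, fell 32.1-fold, from 8.73 ± 10.3 to 0.267 ± 0.153 TPM, with an SD above its mean at 34 °C and a call lost on log2(TPM + 5) (adjusted p from 0.000731 to 0.055). Slc25a47, a mitochondrial carrier, fell 9.85-fold, Snora41 7.12-fold and H2-Q5 2.13-fold.

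Splicing regulators went both ways in DMSO. Of 24 hnRNP and PTB genes, 6 rose, 8 fell and 10 were not called (7 and 8 when adjusted over the list alone; 5 fell at the lowest over the scalings and the limma fit of log2(TPM + 1)). Hnrnpdl fell 2.9-fold, from 136 ± 4.03 to 60.4 ± 9.87 TPM (adjusted p = 2.7e-05) and Hnrnpa1 fell 2.07-fold, from 129 ± 17.2 to 54.1 ± 5.42 TPM, while Hnrnph3 rose 2.28-fold (adjusted p up to 0.0503, on log2(TPM + 5)) and Hnrnpm 1.57-fold. Camera gave an adjusted p = 0.954, with a median of 0.02, a mean of -0.05 and a test that pointed down. Of 31 other RNA-binding and core splicing genes, 6 rose and 5 fell (7 and 5 adjusted over the list alone; 3 fell at the lowest over the same alternatives; adjusted p = 0.954). Tardbp, which encodes TDP-43, rose 2.23-fold, from 70.4 ± 8.76 to 239 ± 35.5 TPM, and Fus fell 2.2-fold, from 162 ± 30.8 to 61.9 ± 2.99 TPM. Of 12 SR protein and Tra2 genes, the activators of exon inclusion, 3 rose and none fell (adjusted p = 0.954). Tra2a rose 1.82-fold, from 17.3 ± 3.25 to 33.8 ± 6.17 TPM, and Srsf9 rose 1.35-fold. Srsf3, Srsf5, Srsf10 and Tra2b were not called, with adjusted p = 0.11, 0.1, 0.24 and 0.3. Of 8 splicing kinase genes, whose products phosphorylate SR proteins, 1 rose and 1 fell (median 0.02, mean -0.01, test downward, adjusted p = 0.96). Clk1 stood at 51 ± 8.28 TPM at 34 °C and 50.9 ± 8.55 TPM at 38 °C (adjusted p = 0.73), and Clk4 had an adjusted p = 0.089. Of 15 NMD factor genes 1 rose (adjusted p = 0.954). Upf3b, Gas5, Atf4 and Alb were not called, with adjusted p = 0.66, 0.63, 0.89 and 0.3.

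Metabolic and stress lists in DMSO did not pass as sets. Of 18 NRF2 target genes, which serve glutathione and thioredoxin metabolism, 3 rose and 8 fell (median log2 -0.36, or -0.23 at the nearest to 0 over the scalings and the limma fit of log2(TPM + 1); adjusted p = 0.736). Beside Gclc, the sulfiredoxin Srxn1 fell 3.02-fold, from 1020 ± 77.8 to 356 ± 8.05 TPM, the thioredoxin reductase Txnrd1 fell 2.46-fold, from 245 ± 30.2 to 101 ± 3.61 TPM, and the efflux transporter Abcc4 fell 2.19-fold. Of 16 metallothionein and hypoxia genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone; median 0.67, adjusted p = 0.133). Egln3 and Egln1, the prolyl hydroxylases that mark hypoxia-inducible factor for decay, rose 3.66-fold and 2.19-fold, and Pfkfb3, a regulator of glycolysis, rose 2.55-fold. Of 15 hepatocyte transcription factor genes, none rose and 5 fell (median -0.38, or -0.24 at the nearest to 0; adjusted p = 0.285), with Cebpa down 1.75-fold, from 30.2 ± 0.902 to 19.1 ± 1 TPM and Hnf4a down 1.75-fold, from 63.5 ± 4.26 to 35.8 ± 1.38 TPM. Of 21 NF-kB and chemokine genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.577), among them Ccl2, which rose 1.71-fold, from 534 ± 18.6 to 954 ± 21.3 TPM. Of 17 circadian clock genes, 2 rose and 6 fell (2 and 7 adjusted over the list alone; 3 fell at the lowest over the scalings and the limma fit of log2(TPM + 1); adjusted p = 0.827). Kupffer cell and macrophage markers were 2 lower of 12, with Cd68 at adjusted p = 0.011 and Cd5l at 0.02 (adjusted p = 0.954 for the list). The call of Cd68 was lost without replicate 1 of 34 °C DMSO (adjusted p from 0.00343 to 0.0598), and that of Cd5l without any 1 replicate of 34 °C DMSO or replicate 1 or 2 of 38 °C DMSO, or on log2(TPM + 0.1) or log2(TPM + 1) (0.00811 to 0.113).

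**Figure D2:**
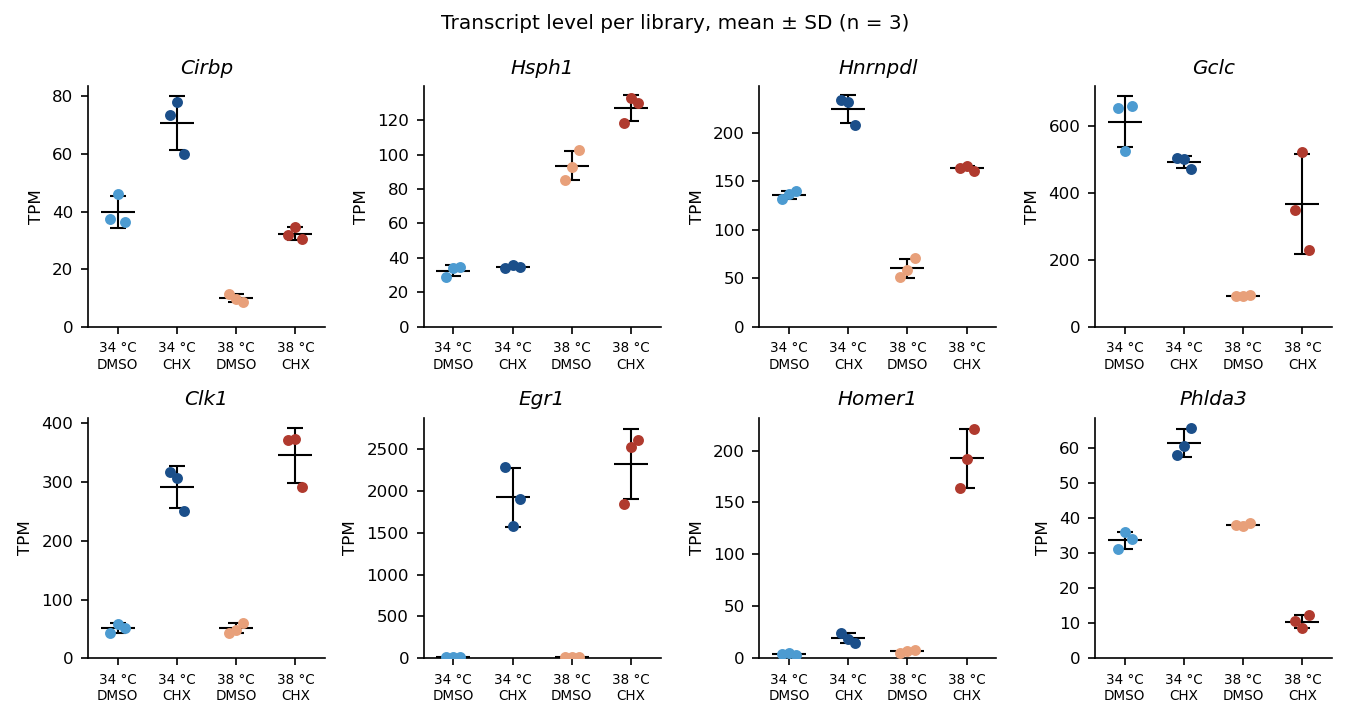
TPM per library (points) with the mean ± SD of n = 3 (bars) for 8 genes in the 4 groups. Cirbp falls and Hsph1 rises at 38 °C under both additions, while Gclc falls to 92.8 TPM in 38 °C DMSO and Homer1 reaches 192 TPM in 38 °C CHX.

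In CHX, the same temperatures were compared to ask which differences are seen when translation, and with it NMD, is stopped. Hsph1 again rose, 3.93-fold, from 34.8 ± 0.777 to 127 ± 7.45 TPM (adjusted p = 8.6e-07), and Cirbp again fell, 2.85-fold, from 70.6 ± 9.41 to 32.3 ± 2.25 TPM (adjusted p = 1e-05). Homer1, a scaffold protein of synapses, rose 9.51-fold, from 19.2 ± 4.89 to 192 ± 28.4 TPM (adjusted p = 2.6e-06), and Phlda3, a p53 target that restrains Akt, fell 6.07-fold, from 61.5 ± 3.99 to 10.5 ± 1.85 TPM (adjusted p = 1.4e-06). The p53 target genes were 2 higher and 10 lower of 15, with a median log2 change of -0.61.

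The edgeR test called 2959 genes higher and 2353 lower at 38 °C in CHX, 5312 in all (40.5%). The balance turned in 4 of 28 alternatives, among them no scaling beyond totals, with 2284 and 3117. At least 2-fold changes numbered 689 up and 578 down. Camera with an estimated correlation passed 0 of 35 lists, with 5 below 0.05 before adjustment, against 8 lists with the preset correlation and 15 with fry. The p53 target list had an adjusted p = 0.116. Ccng1, cyclin G1, fell 3.87-fold, from 152 ± 8.8 to 39.2 ± 1.17 TPM, and Eda2r, a receptor induced by p53, fell 3.36-fold. Of 25 heat shock response genes, 13 rose and 1 fell (median 0.48, adjusted p = 0.116). Stip1 rose 1.46-fold, the small chaperone Hspb8 1.71-fold, and Hspa1b 4.83-fold (adjusted p = 0.0012). Hspa1a rose 2.85-fold (adjusted p = 0.013) and Hsp90aa1 rose 1.45-fold (adjusted p = 0.0038), a call again lost in all 4 limma fits of log2 TPM and kept on log2 scaled counts (0.00138 to 0.186). Of 16 metallothionein and hypoxia genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone; median 1.26, adjusted p = 0.116). Pfkfb3 rose 8.73-fold, from 6.27 ± 1.25 to 43.8 ± 3.4 TPM, Ankrd37 rose 10.7-fold, and Vegfa, the angiogenic growth factor, rose 3.82-fold, from 66.3 ± 3.42 to 220 ± 25.5 TPM. Of 25 ribosome biogenesis genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; adjusted p = 0.196), and the nucleolar Gnl3 rose 2.64-fold.

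Splicing regulators that rose outnumbered those that fell in CHX, but none of their lists passed. Of 24 hnRNP and PTB genes, 10 rose and 5 fell (12 and 5 adjusted over the list alone; median 0.30, adjusted p = 0.91). Hnrnpu rose 2.21-fold, from 200 ± 20.6 to 437 ± 46.5 TPM, Hnrnph3 rose 2.38-fold, and Hnrnpa1 fell 2.05-fold. Of 31 other RNA-binding and core splicing genes, 11 rose and 3 fell (12 and 3 adjusted over the list alone; adjusted p = 0.91). Tardbp rose 2.24-fold, from 103 ± 15.2 to 316 ± 35.2 TPM, and Luc7l3, a partner of the U1 particle, rose 3.12-fold, from 24.2 ± 6.55 to 87.7 ± 6.81 TPM. Of 8 splicing kinase genes, 6 rose, and 2 at the lowest over the scalings and the limma fit of log2(TPM + 1) (median 0.39, adjusted p = 0.291), Prpf4b by 1.77-fold and Clk2 by 1.41-fold. Clk1 and Clk4 were not called (adjusted p = 0.14 and 0.13). Of 12 SR protein and Tra2 genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.91). Srsf3 and Srsf5 were lower at 38 °C, with log2 changes of -0.66 ± 0.16 (SE) and -0.54 ± 0.13 and an adjusted p = 0.0059 for both. Srsf10 was higher (log2 0.6 ± 0.17, adjusted p = 0.014), and its call was lost without replicate 3 of 34 °C CHX or replicate 2 of 38 °C CHX, with adjusted p up to 0.0616. Of 15 NMD factor genes, 6 rose (3 at the lowest over the same alternatives) and 2 fell (median -0.03, mean 0.11, test upward, adjusted p = 0.91). Upf3b, which joins the decay factors to exon junctions, rose (log2 0.6 ± 0.2, adjusted p = 0.035). Its call was lost without replicate 1 or 3 of 34 °C DMSO, 2 or 3 of 34 °C CHX, or 1 or 2 of 38 °C CHX, and with replicate number as a term, with adjusted p up to 0.133. Rbm3, Tra2b, Gas5, Atf4 and Alb were not called, with adjusted p = 0.19, 0.41, 0.17, 0.25 and 0.062.

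Other large rises in CHX were Ffar4, a fatty acid receptor, which rose 9.49-fold, from 1.83 ± 0.153 to 17.3 ± 2.73 TPM, Banp, which rose 13-fold, Trim17 (5.82-fold), and the histone genes Hist1h2br (8.96-fold) and Hist1h3d (6.18-fold), which are hard to tell from other histone copies. Large falls included the interferon-induced Ifit3, which fell 6.14-fold, from 263 ± 100 to 43.2 ± 12.1 TPM, Ifit1 (6.13-fold), Ifit3b (5.13-fold) and Oasl1 (4.02-fold). Txnip, which binds thioredoxin, fell 6.11-fold, from 442 ± 191 to 72.4 ± 18.3 TPM, Gtse1, a regulator of the cell cycle, fell 10.3-fold, from 11.2 ± 0.987 to 1.07 ± 0.115 TPM, and Mrap, a partner of the ACTH receptor, fell 5.38-fold. The ATF4 and integrated stress list had 25 tested entries, because members were matched by symbol and Ddit3 has a second Ensembl entry. Of these, 14 rose and 3 fell (15 and 4 adjusted over the list alone, camera's adjusted p = 0.471). Mthfd2, of mitochondrial folate metabolism, rose 2.86-fold and Vldlr, a lipoprotein receptor, 3.72-fold, while Sesn2, an inhibitor of mTORC1 signalling, fell 3-fold. Of 18 NRF2 target genes 2 rose and 3 fell (2 and 2 adjusted over the list alone; median -0.15, mean 0.00, test downward, adjusted p = 0.91), and Hmox1, which degrades haem, rose 4.17-fold, from 151 ± 14.7 to 628 ± 165 TPM. Of 15 hepatocyte transcription factor genes, 2 rose and 9 fell (median -0.44, or -0.28 at the nearest to 0 over the scalings and the limma fit of log2(TPM + 1); adjusted p = 0.461). Of 24 cholesterol synthesis genes, 1 rose and 8 fell (1 and 7 adjusted over the list alone; median -0.25, adjusted p = 0.756), with Fdft1, squalene synthase, down 1.74-fold, from 99.7 ± 2.83 to 54.8 ± 4.45 TPM.

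The temperature responses of DMSO and CHX shared more calls than independent calls would give. Of the genes called in both, 695 were higher (311.8 expected) and 564 lower (245.6 expected) at 38 °C in each. Opposite calls were made for 71 genes higher and 157 lower in DMSO, all with an interaction call. The log2 changes correlated across genes, which are not independent replicates, at Pearson 0.338 (0.212 to 0.443 over the alternatives but for DESeq2, which gave 0.097) and Spearman 0.383. Genes higher at 38 °C in DMSO had a median log2 change of 0.568 in DMSO and 0.364 in CHX, and those lower had medians of -0.653 and -0.305. Genes called in CHX went the other way, with medians of 0.669 in CHX and 0.143 in DMSO for those higher and of -0.673 and -0.201 for those lower, so either set looks larger in the comparison that picked it. A total least squares line over all genes had a slope of 2.172, with larger changes in CHX. The slope was 1.578 without replicate 3 of 38 °C CHX, 1.567 with array weights and 8.568 with DESeq2, so its size is not firm. At so low a correlation it also follows the spread of the changes in each treatment.

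At 34 °C, CHX was set against DMSO to ask which RNAs change when translation stops. Immediate early genes, which growth signals induce without new protein, were higher with CHX in 23 of 24 cases, with a median log2 change of 3.08. Egr1, a transcription factor, rose 126-fold, from 14.9 ± 1.9 to 1920 ± 351 TPM (adjusted p = 1.2e-09). Splicing regulators were mostly higher: 10 of 12 SR protein and Tra2 genes were higher and 1 was lower, and the kinase gene Clk1 rose 6.25-fold, from 51 ± 8.28 to 292 ± 36.3 TPM (adjusted p = 2.8e-07). Markers of Kupffer cells and macrophages, the resident phagocytes of liver, were lower in 10 of 12 cases, and Cd5l fell 3.9-fold, from 32.2 ± 2.41 to 8.47 ± 0.153 TPM (adjusted p = 7.5e-08). Alb fell 1.35-fold, from 32200 ± 1540 to 24500 ± 603 TPM (adjusted p = 0.0013); limma on log2 scaled counts did not call it (adjusted p = 0.184), and quantile scaling, which sets the highest gene of each library to 1 value, leaves it no change.

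The edgeR test called 3266 genes higher and 3043 lower with CHX at 34 °C, 6309 in all (48.1%). The balance turned in 4 of 28 alternatives, among them quantile scaling, with 2744 and 3667. By at least 2-fold, 1382 rose and 549 fell. Of 35 lists, 7 passed camera's test with an estimated correlation, against 15 with the preset correlation and 24 with fry: splicing kinase, NMD factor, immediate early, NF-kB and chemokine, p53 target and Kupffer cell genes, each at adjusted p = 0.0343, and replication-dependent histone genes at 0.0417. All 7 calls were lost with camera on log2(TPM + 0.1) (adjusted p from 0.0773 to 0.154), on log2(TPM + 1) (0.099 to 0.147) and on log2 scaled counts (0.0527 to 0.0558), and replicate number as a term ended all but that of the histone genes. The calls also depended on single libraries. No list passed without any 1 of 34 °C DMSO replicate 3, 38 °C DMSO replicates 1, 2 or 3, or 38 °C CHX replicates 2 or 3, 2 passed without 34 °C DMSO replicate 2, and 4 without 34 °C DMSO replicate 1.

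Splicing kinase genes were 5 higher of 8 (median 0.92), and Clk4 rose 5.94-fold, from 23.4 ± 1.45 to 150 ± 2.84 TPM (adjusted p = 2e-08), Dyrk1a 2.32-fold and Clk3 2.27-fold. NMD factor genes were 12 higher and none lower of 15 (13 adjusted over the list alone, and 7 at the lowest over the scalings and the limma fit of log2(TPM + 1); median 0.49). Smg8, which regulates the NMD kinase, rose 2.18-fold, from 11.4 ± 0.551 to 25.8 ± 0.1 TPM, Smg7, which binds phosphorylated Upf1, 1.84-fold, and the exon junction proteins Casc3 and Rbm8a 2.03-fold and 1.64-fold. Upf3b was not called (adjusted p = 0.73). The SR protein and Tra2 list (11 and 1 adjusted over the list alone; median 1.19) had a preset adjusted p = 1.28e-05 and an adjusted p = 0.187 with an estimated correlation. Tra2b rose 3.42-fold, from 28.8 ± 2.87 to 112 ± 10.4 TPM, Srsf3 rose 3.21-fold, from 78.5 ± 17.8 to 275 ± 22.8 TPM, and Tra2a, Srsf7, Srsf5 and Srsf10 rose 4.26-fold, 2.63-fold, 2.2-fold and 1.96-fold. Of 31 other RNA-binding and core splicing genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone; median 0.68; preset 3.23e-07, adjusted p = 0.183 with an estimated correlation). Rbm5 rose 4.78-fold, from 24.7 ± 2.08 to 122 ± 6.94 TPM, and Rbm39 rose 4.52-fold, from 78.3 ± 9.5 to 338 ± 42.1 TPM. Of 24 hnRNP and PTB genes, 13 rose and none fell (median 0.36, adjusted p = 0.482), and Hnrnph1 rose 3.57-fold, from 58.9 ± 10.5 to 279 ± 49.8 TPM. Cirbp rose 1.79-fold (adjusted p = 0.00019), and Rbm3 was not called (adjusted p = 0.81). Gas5, a snoRNA host known as an NMD target, was not called (adjusted p = 0.81). Atf4, the stress transcription factor, rose 3.34-fold, from 256 ± 16.4 to 881 ± 66 TPM.

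NF-kB and chemokine genes were higher with CHX at 34 °C in all 21 cases (median 2.48). Tnfaip3, a feedback inhibitor of NF-kB, rose 35.4-fold, from 6.77 ± 0.416 to 242 ± 21.4 TPM, and the chemokine gene Cxcl2 rose 57.7-fold, from 11.1 ± 1.97 to 727 ± 72.1 TPM. The stress factor Atf3 rose 55.7-fold, from 45.7 ± 10.2 to 2600 ± 301 TPM, and the immediate early genes Fos, Jun, Btg2 and Ier2 rose 62.9-fold, 32.9-fold, 33.7-fold and 37.9-fold. Of 15 p53 target genes, 13 rose and 1 fell (median 0.85). Mdm2, the ligase that degrades p53, rose 6.56-fold, from 44.5 ± 2.7 to 288 ± 17.4 TPM, and the cell cycle inhibitor Cdkn1a rose 6.55-fold, from 96.4 ± 4.5 to 648 ± 62.2 TPM. All 9 replication-dependent histone genes rose (median 5.31, or 1.79 at the lowest over the scalings and the limma fit of log2(TPM + 1); Hist1h1a and Hist1h1b, named after their values were seen, had 1 and 3 counts in DMSO), with Hist1h1c up 18.2-fold, from 51.4 ± 7.03 to 965 ± 48.4 TPM and Hist1h4i 128-fold, although polyA selection keeps few of these RNAs and their copies are hard to tell apart. Hist1h3d, with 0 counts in DMSO and 535 in CHX, was at least 178-fold higher.

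The markers of other cells moved beside these lists. The Kupffer cell list had a median of -2.04, with Clec4f down 5.82-fold, C1qc 4.95-fold, Vsig4 8.21-fold and the lysozyme gene Lyz2 down 6.17-fold, from 44.1 ± 10.6 to 7.33 ± 1.54 TPM. Of 9 liver endothelial cell genes none rose and 4 fell (adjusted p = 0.437), with Fcgr2b down 3.03-fold. Other large falls were the noncoding RNA Dancr, down 9.52-fold, from 18.2 ± 0.85 to 2.33 ± 0.551 TPM, G0s2, an inhibitor of lipolysis, down 9.13-fold, from 15.2 ± 3.38 to 1.7 ± 0.52 TPM, Wfdc17, down 5.8-fold, and Dpm1, down 3.75-fold by counts. The snoRNA gene Snora57 fell from 85 counts to 1 (85.3-fold, counting interval 14.9 to 3410), and Snora69 from 9 to 0 (at least 3.01-fold lower), whose call was lost without replicate 2 or 3 of 34 °C DMSO or any 1 replicate of 34 °C CHX, and with replicate number as a term, with adjusted p up to 0.115. Hspa1a rose 2.48-fold (adjusted p = 0.029), a call lost without any 1 of the 6 libraries of 34 °C, and in all 4 limma fits of log2 TPM, with adjusted p from 0.00901 to 0.495. Hsp90aa1 rose 1.37-fold (adjusted p = 0.0078), a call that quantile scaling ended (0.00308 to 0.0939), and Hspa1b was not called (adjusted p = 0.54). Of 33 secreted plasma protein genes, the main products of hepatocytes, none rose and 22 fell (14 at the lowest over the scalings and the limma fit of log2(TPM + 1); median -0.37, adjusted p = 0.271). Of 80 cytosolic ribosomal protein genes none rose and 33 fell (30 adjusted over the list alone, and 21 at the lowest over the same alternatives; median -0.38, adjusted p = 0.437), and of 39 nuclear-encoded respiratory chain genes none rose and 19 fell (adjusted p = 0.482).

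At 38 °C, CHX was set against DMSO with the same question. Immediate early genes were higher with CHX in all 24 cases, with a median log2 change of 3.22, and Egr1 rose 150-fold, from 15.6 ± 1.45 to 2320 ± 420 TPM (adjusted p = 9.2e-10). The splicing kinase gene Clk4 rose 8.38-fold, from 19.7 ± 3.01 to 164 ± 17.7 TPM (adjusted p = 4.4e-09), and 7 of 8 genes of its list were higher (median 1.42). Cirbp rose 3.22-fold, from 9.93 ± 1.46 to 32.3 ± 2.25 TPM (adjusted p = 6e-07). Markers of Kupffer cells were 1 higher and 10 lower of 12 (median -2.26), and Lgals1, the lectin galectin-1, fell 11.7-fold, from 245 ± 15.4 to 20.8 ± 8.92 TPM (adjusted p = 6.6e-07).

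The edgeR test called 4358 genes higher and 4119 lower with CHX at 38 °C, 8477 in all (64.6%). That balance turned in 12 of 28 alternatives, 6 of them with a single library left out, and the share higher ran from 43.1% to 62.5%. By at least 2-fold, 2363 rose and 1415 fell. Camera passed 0 of 35 lists with an estimated correlation, with adjusted p = 0.0936 at best, for the splicing kinase, immediate early, histone and Kupffer cell genes. Before adjustment 7 lists were below 0.05, and the preset correlation passed 16 lists and fry 29.

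Most measured splicing genes were called higher with CHX at 38 °C. Of 12 SR protein and Tra2 genes, 11 rose and 1 fell (median 1.34, adjusted p = 0.245), with Tra2b up 4.3-fold, from 27.4 ± 4.3 to 127 ± 2.1 TPM, Tra2a 3.91-fold, Srsf11 3.41-fold, Srsf3 2.63-fold, Srsf10 2.42-fold and Srsf5 1.89-fold. Clk1 rose 7.25-fold, from 50.9 ± 8.55 to 346 ± 46.8 TPM, and Dyrk1a rose 3.31-fold. Of 31 other RNA-binding and core splicing genes, 25 rose and 3 fell (median 0.96, adjusted p = 0.245), with Rbm5 up 5.56-fold, Son 3.82-fold and Sf3b1 3.22-fold. Of 24 hnRNP and PTB genes, 16 rose and 2 fell (median 0.63, adjusted p = 0.435), with the neuronal PTB gene Ptbp2 up 5.56-fold and Hnrnpdl 2.81-fold. Of 15 NMD factor genes, 9 rose and none fell (median 0.49, adjusted p = 0.123), with Smg8 up 2.73-fold, Smg1, the NMD kinase, 2.42-fold and Casc3 2.39-fold. Upf3b rose (log2 0.55 ± 0.2, adjusted p = 0.033), a call lost without any 1 replicate of 34 °C DMSO or without replicate 1 or 2 of 38 °C DMSO or of 38 °C CHX, and with quantile scaling or replicate number as a term, with adjusted p up to 0.163. Atf4 rose 3.07-fold, Hsp90aa1 rose 1.35-fold (adjusted p = 0.0064) and Alb fell 1.28-fold (adjusted p = 0.0031), the last a call lost with quantile scaling of log2 TPM and with limma on log2 scaled counts (0.00104 to 0.325). Rbm3, Hspa1a, Hspa1b and Gas5 were not called, with adjusted p = 0.076, 0.41, 0.27 and 0.071.

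Egr2 rose 420-fold with CHX at 38 °C, Trim17 452-fold, Fos 75.5-fold and Atf3 56.4-fold. Of 21 NF-kB and chemokine genes 18 rose and none fell (median 1.85, adjusted p = 0.139), with Cxcl2 up 42.8-fold and Tnfaip3 26.9-fold. Of 17 circadian clock genes, 14 rose and none fell (median 1.33, adjusted p = 0.239), with Nr1d1, the repressor REV-ERB alpha, up 15.2-fold and Per1 11.2-fold. Of 15 p53 target genes 7 rose and 6 fell (median -0.23, mean 0.73, test upward, adjusted p = 0.618), with Mdm2 up 3.95-fold and Cdkn1a 3.36-fold. All 9 histone genes rose (median 4.98, or 4.54 with 1 gene at its counting bound and 2.98 at the lowest over the scalings and the limma fit of log2(TPM + 1)), and Hist1h3d went from 3 counts to 3194 (1010-fold, counting interval 344 to 4880) and Hist2h3c1 rose 143-fold. A second Ensembl entry of Ddit3 went from 1 count to 114 (108-fold, 19 to 4290). Of 14 cell cycle genes 2 rose and 8 fell (median -0.99, adjusted p = 0.139), with Mcm5, of the replicative helicase, down 10.1-fold, from 18.7 ± 2.7 to 1.73 ± 0.751 TPM. Of 80 cytosolic ribosomal protein genes none rose and 63 fell (median -0.57, adjusted p = 0.361), and of 39 respiratory chain genes none rose and 33 fell (median -0.59, adjusted p = 0.361). Among the Kupffer cell markers Clec4f fell 7.55-fold and Cd5l 4.19-fold. Lyz2 fell 8.37-fold, from 56.5 ± 5.02 to 6.67 ± 1.63 TPM, the calcium-binding S100a6 9.35-fold, S100a4 12.6-fold and Dpm1 3.99-fold. Snora57 went from 45 counts to 3 (15.9-fold lower, 5.09 to 79.8), and Snord22 from 9 to 0 (at least 3.17-fold lower).

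The CHX responses at the temperatures shared 2827 higher and 2433 lower genes, where independent calls would share 1085 and 955.8. Opposite calls numbered 60 and 94. Across genes, which are not independent replicates, Pearson's r was 0.772 (0.572 to 0.859 over the alternatives) and Spearman's rho 0.78. A total least squares line through the log2 changes had a slope of 1.432, with larger changes at 38 °C. That slope also follows the spread of the changes at each temperature. Genes higher with CHX at 34 °C had a median of 0.879 at 34 °C and 1.156 at 38 °C, and those lower had medians of -0.614 and -0.77. Genes called at 38 °C had medians of 1.074 at 38 °C and 0.623 at 34 °C when higher, and of -0.792 and -0.46 when lower.

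**Figure D3:**
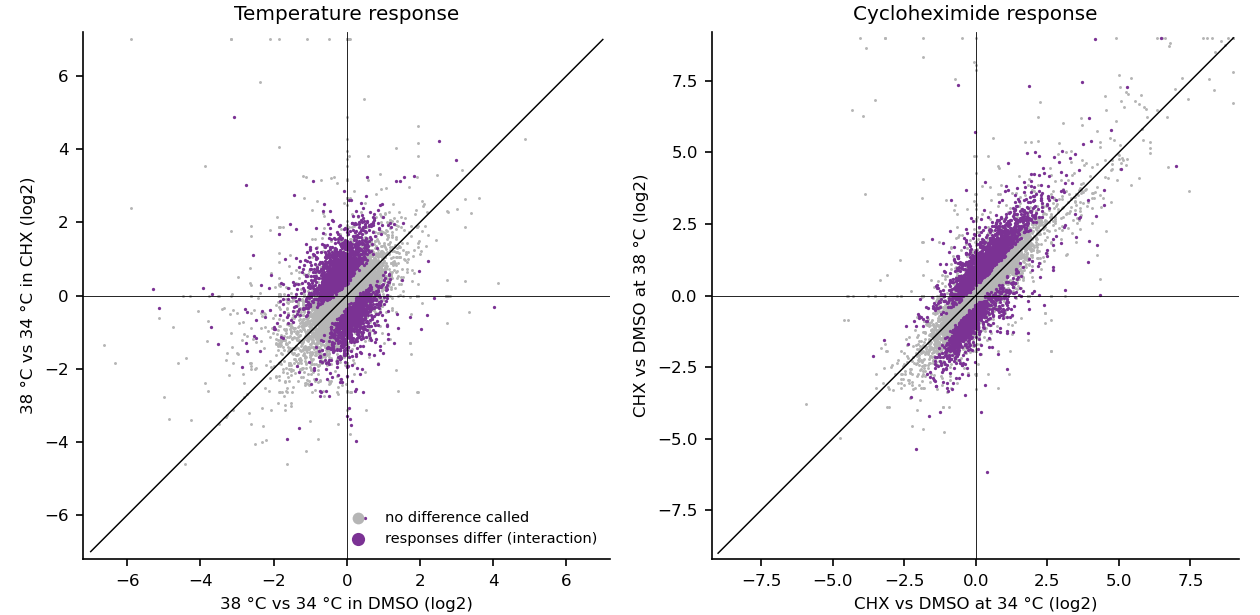
Each point is a gene: log2 change at 38 °C in DMSO against CHX (left) and log2 change with CHX at 34 °C against 38 °C (right), with interaction calls in purple and the line of equality; values beyond the axes are drawn at the edge. Across genes Pearson's r is 0.338 on the left and 0.772 on the right.

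The interaction asks whether CHX changed the temperature response, which is the same as whether temperature changed the CHX response. Gclc, which fell at 38 °C in DMSO, stood at 613 ± 76.4 and 92.8 ± 2.26 TPM in DMSO and at 492 ± 17.8 and 367 ± 148 TPM in CHX at 34 and 38 °C, an interaction of 2.41 ± 0.34 (log2 ± SE, adjusted p = 0.0011). Homer1 stood at 4.23 ± 0.709 and 6.8 ± 1.35 TPM in DMSO and at 19.2 ± 4.89 and 192 ± 28.4 TPM in CHX (2.68 ± 0.3, adjusted p = 0.00041). Phlda3 stood at 33.7 ± 2.46 and 38.2 ± 0.473 TPM in DMSO and at 61.5 ± 3.99 and 10.5 ± 1.85 TPM in CHX (-2.82 ± 0.19, adjusted p = 9e-05). The fall of Cirbp at 38 °C was smaller in CHX (0.85 ± 0.18, adjusted p = 0.0073).

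The edgeR test called 1611 genes with a more positive and 1024 with a more negative temperature response in CHX, 2635 in all (20.1%). This balance turned in 3 of 27 alternatives, among them no scaling beyond totals, with 1150 and 1556. The more positive ones numbered 979 without replicate 2 of 34 °C DMSO and 976 without replicate 2 of 38 °C DMSO. The more negative ones numbered 661, 629 and 605 without replicates 1, 2 and 3 of 34 °C CHX, and 1581 without replicate 3 of 38 °C CHX. The whole count was 1708 without replicate 3 of 34 °C CHX and 3599 without replicate 3 of 38 °C CHX. Genes called in DMSO alone that also had an interaction call numbered 190 higher and 274 lower at 38 °C. The higher ones numbered 118, 103 and 108 without replicates 1, 2 and 3 of 34 °C CHX, 286 without replicate 3 of 38 °C DMSO and 349 without replicate 3 of 38 °C CHX. The lower ones numbered 141, 129 and 131 without replicates 1, 2 and 3 of 34 °C DMSO, 177 without replicate 3 of 34 °C CHX, and 140 and 118 without replicates 1 and 2 of 38 °C DMSO. Genes called in CHX alone with an interaction call numbered 997 higher and 635 lower, the latter 411 and 399 without replicates 2 and 3 of 34 °C CHX. The balance in DMSO alone turned in 15 of 26 alternatives, 6 of them with a single library left out, so it has no firm direction. That in CHX alone turned in 2 of 26, no scaling beyond totals (702 higher and 993 lower) and array weights (864 and 1148). Of genes higher with CHX at both temperatures with an interaction call, 775 of 831 rose more at 38 °C, and of those lower at both, 398 of 433 fell more.

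Camera passed 0 of 35 lists for the interaction with an estimated correlation. Before adjustment 4 lists were below 0.05, the preset correlation passed 17 and fry 14, and with an estimated correlation 2 passed without replicate 2 of 34 °C DMSO and 1 without replicate 2 of 38 °C CHX. Of 15 p53 target genes, 2 were called positive and 7 negative (2 and 11 adjusted over the list alone; median -0.72, adjusted p = 0.101), with Ccng1 at -1.67 ± 0.18. Of 14 cell cycle genes, 1 was positive and 6 negative (1 and 9 adjusted over the list alone; median -0.67, or -0.36 at the nearest to 0 over the scalings and the limma fit of log2(TPM + 1); adjusted p = 0.101), with Mcm2, of the replicative helicase, at -1.64 ± 0.17. Of 24 cholesterol synthesis genes none was positive and 9 negative (13 adjusted over the list alone; median -0.50, adjusted p = 0.341), with Hmgcs1 at -1.01 ± 0.18. Of 17 circadian clock genes, 8 were positive (10 adjusted over the list alone, and 3 at the lowest over the scalings and the limma fit of log2(TPM + 1); median 0.83, adjusted p = 0.341), with the clock repressor Cry1 at 1.2 ± 0.14. Of 18 NRF2 target genes, 5 were positive and 1 negative (7 and 1 adjusted over the list alone; adjusted p = 0.663), with Srxn1 at 1.79 ± 0.21 and Txnrd1 at 1.19 ± 0.23 beside Gclc.

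Splicing lists held interaction calls without passing as sets, beside calls for 20.1% of all genes. Of 12 SR protein and Tra2 genes only Srsf7 was called, at -0.49 ± 0.09, and the list's median turned sign with the scaling (adjusted p = 0.997). Srsf3, Srsf5, Srsf10 and Tra2b were not called, with adjusted p = 0.4, 0.42, 0.39 and 0.21. Of 24 hnRNP and PTB genes 5 were positive (3 at the lowest over the same alternatives) and 1 negative (adjusted p = 0.769), with Hnrnpdl at 0.86 ± 0.15 and Ptbp2 at 1.3 ± 0.27. Of 31 other RNA-binding and core splicing genes 6 were positive (3 at the lowest) and 1 negative (adjusted p = 0.872), with Fus at 0.81 ± 0.14 and Rbm10 at -0.98 ± 0.13. Of 8 splicing kinase genes 4 were positive, and 0 at the lowest over the scalings and the limma fit of log2(TPM + 1) (median 0.48, adjusted p = 0.341), with Dyrk1a at 0.51 ± 0.11. Clk4 was at 0.5 ± 0.15 (adjusted p = 0.04), a call lost without any 1 library except replicate 3 of 38 °C DMSO or of 38 °C CHX, in all 4 limma fits of log2 TPM and with replicate number as a term, with adjusted p from 0.00787 to 0.141. Of 15 NMD factor genes 1 was positive (median 0.00, of a sign that turned with the scaling, adjusted p = 0.997), with Smg1 at 0.75 ± 0.16. The calls of Dyrk1a (adjusted p from 0.00605 to 0.0873) and Smg1 (0.00543 to 0.0838) were also lost in all 4 limma fits of log2 TPM and kept on log2 scaled counts. Rbm3, Hspa1a, Hspa1b, Hsp90aa1, Clk1, Gas5, Atf4, Upf3b and Alb were not called, with adjusted p = 0.4, 0.3, 0.32, 0.97, 0.54, 0.23, 0.59, 0.3 and 0.68.

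**Figure D4:**
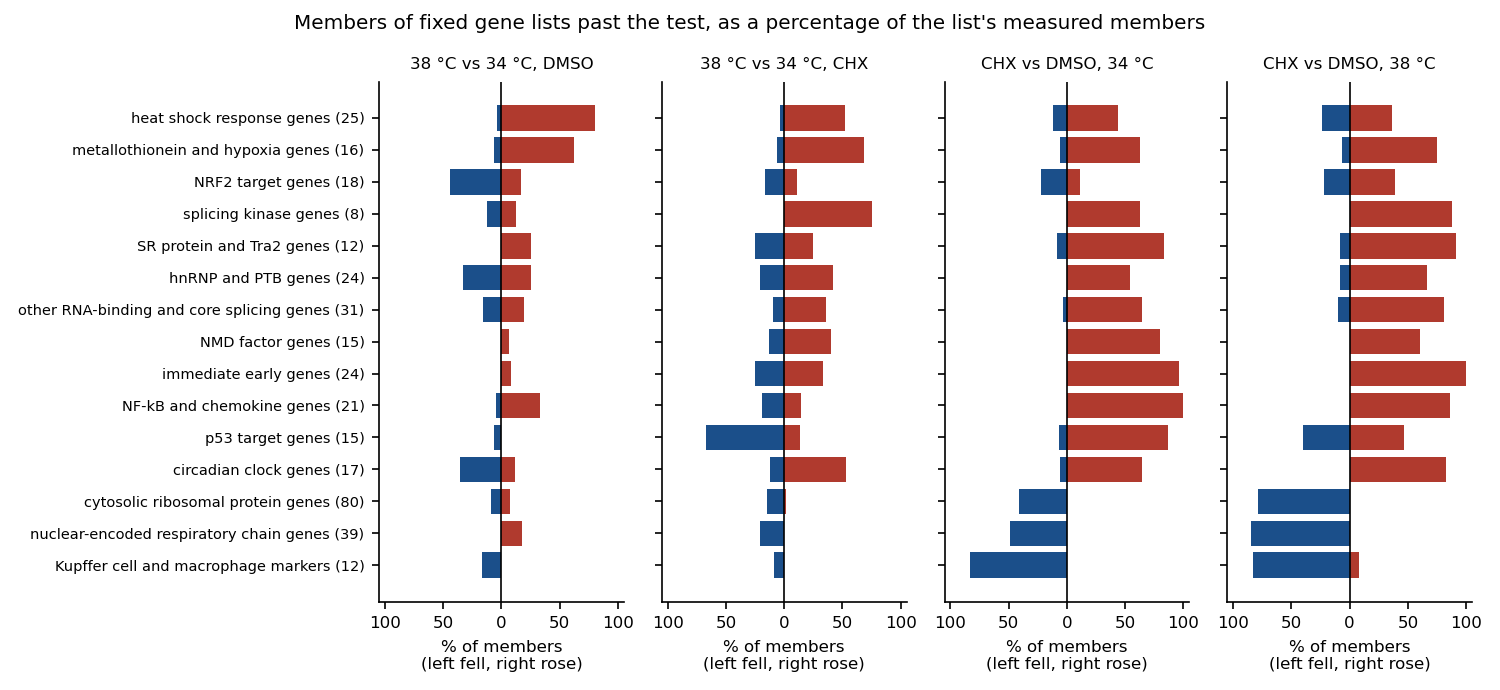
Percent of the measured members of 15 gene lists called higher (right) and lower (left) in each of the 4 pairwise comparisons, with the number of measured members beside each list. Heat shock response genes are higher at 38 °C in DMSO in 20 of 25 cases, and Kupffer cell markers are lower with CHX at 34 °C in 10 of 12.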

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

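The tests of strand, depth and sample label for replicate 3 of 38 °C CHX were chosen only after the values of that library were seen, and so was the condition that an annotated NMD share must also lie below the range of matched lists, and not only at or below their median, to count against NMD.

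The temperature response differed between DMSO and CHX by the interaction test for 2635 of 13114 genes, 31 of the named genes among them, with 1708 without replicate 3 of 34 °C CHX. Residuals of the libraries from the additive model were put in 100 arrangements and tested with limma on log2 scaled counts. Of these, 1 gave as many genes, the real one with 2676, and the highest other gave 1307. With 100 arrangements the share cannot fall below 1 in 100. The test also treats the residuals of all libraries as exchangeable, although 1 library stood apart from its group mates. It therefore does not exclude chance for this count. The groups hold 3 libraries each, too few for a test of single outlying libraries.

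Genes with a more positive temperature response in CHX, as log2 interaction ± SE, were these. Igfbp1, a liver-secreted binding protein of insulin-like growth factors, had 2.96 ± 0.43, from 230 ± 83.4 to 154 ± 34.6 TPM in DMSO and from 109 ± 13.3 to 544 ± 185 TPM in CHX. Areg, a ligand of the EGF receptor, had 2.7 ± 0.35, from 14.5 ± 3.41 to 8.4 ± 1.18 TPM in DMSO and from 14 ± 0.651 to 50.8 ± 16.4 TPM in CHX. Leap2, which encodes a peptide that blocks the ghrelin receptor, had 2.51 ± 0.4, and stood at 17.1 ± 4.65 TPM in 38 °C DMSO and 109 ± 41.6 TPM in 38 °C CHX. Homer1 had 2.68 ± 0.3, Gclc 2.41 ± 0.34 and Hamp 2.19 ± 0.45. Chac1, which degrades glutathione, had 2.34 ± 0.3, with 23.3 ± 5.13 TPM in 38 °C CHX against 7.13 ± 1.11 TPM in 34 °C CHX. Rgs16, a regulator of G-protein signals, had 2.64 ± 0.58, Cirbp 0.85 ± 0.18 and the splicing kinase gene Clk4 0.5 ± 0.15, whose call was lost without any 1 library except replicate 3 of 38 °C DMSO or of 38 °C CHX, in all 4 limma fits of log2 TPM and with replicate number as a term (adjusted p from 0.00787 to 0.141). Srxn1 had 1.79 ± 0.21, Ptbp2 1.3 ± 0.27, Cry1 1.2 ± 0.14, Txnrd1 1.19 ± 0.23, Hnrnpdl 0.86 ± 0.15 and Fus 0.81 ± 0.14. Smg1 had 0.75 ± 0.16 and Dyrk1a 0.51 ± 0.11, calls lost in all 4 limma fits of log2 TPM.

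Genes with a more negative temperature response in CHX were these. Ccl20 had -4.34 ± 0.61, from 0.4 ± 0.1 to 7.27 ± 1.64 TPM in DMSO and from 8.93 ± 0.451 to 7.23 ± 3.95 TPM in CHX. Gtse1 had -3.45 ± 0.25, Cib3 -2.94 ± 0.4 and Phlda3 -2.82 ± 0.19. Serpine1 had -2.75 ± 0.44, with 471 ± 90.9 TPM in 34 °C CHX and 323 ± 125 TPM in 38 °C CHX. Ddit4, an inhibitor of mTORC1, had -2.55 ± 0.3, from 14.3 ± 2.3 to 29.3 ± 8.98 TPM in DMSO and from 36 ± 3 to 12.2 ± 1.65 TPM in CHX. Mcm5 had -2.39 ± 0.32 and the interferon-induced Ifit3b -2.19 ± 0.47. Ccng1 had -1.67 ± 0.18, Mcm2 -1.64 ± 0.17, Hmgcs1 -1.01 ± 0.18, Rbm10 -0.98 ± 0.13 and Srsf7 -0.49 ± 0.09.

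In replicate 3 of 38 °C CHX, 101 genes stood more than 16-fold below and 54 more than 16-fold above the mean of the group mates. The higher of the compared levels had to be at least 20 TPM. Low depth and a wrong label are argued against: the group mates' level would have given the median lower gene 780 counts in this library, and over genes with no annotated overlap its lowest correlation with a group mate was 0.982, above the 0.963 of the best library of another group. Of the lower genes, 61.4% lay mostly over exons of the other strand, against 1.92% of all genes at that level, so reads assigned by strand in this library and not in the others are a candidate explanation. Of the higher genes 33.3% did, against 1.27%, which leaves them open, and 30 of the 54 had under 30 counts. No biological explanation was tested, since the design names no difference between the replicates.

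Across genes, the CHX response was larger at 38 °C than at 34 °C by a total least squares slope of 1.432. Such a slope also follows the spread of the changes at each temperature. Lists went both ways: the median of immediate early genes was 3.08 at 34 °C and 3.22 at 38 °C, and that of NF-kB and chemokine genes 2.48 and 1.85. The slope was 1.378 without replicate 3 of 38 °C CHX and 1.351 over protein-coding genes with no annotated overlap, which argues against that library or reads of overlapping genes as the whole source. When the 34 °C response was scaled by the common slope, 42.1% of the interaction calls (1109) were left and 1412 genes were called. The 1412 genes were called against a factor of 1.432 taken as known, although it ran from 1.351 to 1.56 over the alternatives. They include genes with no interaction call. The share left lay between the limits set beforehand, so a single common factor stays open. For the interaction calls that were lost, such a factor cannot be told apart from gene-specific differences, since the scaling also adds error to the contrast. A biological effect of temperature on the action of CHX or on RNA decay stays open and was not tested.

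Some temperature responses were seen in DMSO and not in CHX, 274 lower (118 without replicate 2 of 38 °C DMSO at the lowest) and 190 higher (103 without replicate 2 of 34 °C CHX to 349 without replicate 3 of 38 °C CHX) at 38 °C with an interaction call. Without replicate 3 of 38 °C CHX, 95.6% of the lower and 93.7% of the higher genes were still called for the interaction. Of all 2635 interaction calls, 2523 were kept without it, so the class was not special in this. Whether the same genes stayed uncalled in CHX without that library was not checked. The class formed anew without it held 404 lower and 349 higher genes, so a class of this kind does not need that library. Its part in the choice of the 274 and 190 genes stays open. NMD of annotated transcripts could give such a class, and then its members should hold more genes with an annotated NMD transcript. The share was 29% (70 of 241) in the lower class, where 95% of 10000 matched lists lay between 23.7 and 33.2% with a median of 28.2%, and 29.7% (55 of 185) in the higher class, where they lay between 28.1 and 38.9% with a median of 33.5%. The share of the higher class lies below that median, the side set beforehand as counting against NMD, but both shares lie within the spread of matched lists, which leaves the explanation open; gene-level counts do not show which transcript was lost.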

How the results depend on the processing

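DESeq2, limma and camera on log2(TPM + 1), limma and camera on log2 scaled counts, totals alone, the genes with no overlap and the reading without replicate 3 of 38 °C CHX were chosen after the data were seen; the other alternatives were planned. Of the counts of genes and of lists, 246 values under an alternative stayed within 1.5 times the main count and 40 moved further. Array weights of limma, which stopped before they converged and gave replicate 2 of 38 °C DMSO a weight of 21.1, called 6133 genes for temperature in DMSO, 4844 for the interaction and 2501 shared by both temperature responses; the cause was not tested. A log2 change of at least 1 left 532 genes for temperature in DMSO, 1267 for temperature in CHX, 1931 for CHX at 34 °C, 3778 for CHX at 38 °C and 887 for the interaction, by its construction. The 6791 protein-coding genes with no annotated overlap gave 3299 for temperature in CHX, 3946 for CHX at 34 °C, 5020 for CHX at 38 °C and 3303 shared by the CHX responses, with fewer genes tested. Leaving out 1 library in turn gave 1811 (without 38 °C DMSO replicate 2) to 3874 (without 38 °C CHX replicate 3) genes for temperature in DMSO, 3926 to 5618 for temperature in CHX, 5066 to 7267 for CHX at 34 °C, 7859 to 8895 for CHX at 38 °C and 1708 (without 34 °C CHX replicate 3) to 3599 (without 38 °C CHX replicate 3) for the interaction. DESeq2 called 3435, 5733, 6637, 8640 and 3348 genes, and limma on log2(TPM + 1) 2447, 4942, 5753, 8157 and 2153. Replicate numbers did not pair the samples as a whole (18 same-number pairs of residuals, median correlation -0.012, against -0.002 for other numbers). Between 34 °C DMSO and 38 °C DMSO the same-number correlations were 0.298, 0.055 and 0.118, and the others ran from -0.253 to 0.167, so pairing stays open there. The replicate block called 2374, 4996, 6000, 8289 and 2160.

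The gene list tests moved most. With the preset correlation 8 lists passed for temperature in DMSO, 8 for temperature in CHX, 15 for CHX at 34 °C, 16 for CHX at 38 °C and 17 for the interaction; with fry 8, 15, 24, 29 and 14. Camera on log2(TPM + 0.1) and on log2(TPM + 1) left 0 lists for temperature in DMSO and 0 for CHX at 34 °C, and on log2 scaled counts 1 and 0. Each of these inputs adds a small value before the log. For CHX at 34 °C the fits therefore cannot part the pseudocount from the log scale. The replicate block left 1 for CHX at 34 °C; the cause was not tested. Leaving out 1 library gave 0 to 7 lists for CHX at 34 °C (0 without 34 °C DMSO replicate 3, 38 °C DMSO replicates 1, 2 or 3, or 38 °C CHX replicates 2 or 3) and 0 to 2 for the interaction (2 without 34 °C DMSO replicate 2, 1 without 38 °C CHX replicate 2). The median of all genes, at 0 for CHX at 38 °C and for the interaction, became -0.109 for CHX at 38 °C under quantile scaling, and -0.152 for CHX at 38 °C and -0.114 for the interaction with totals alone. Of the named genes, 4715 results under an alternative kept their call and direction, 90 lost the call, 20 gained one and 1 turned: Alb with CHX at 34 °C was at 0 under quantile scaling, by construction, since that scaling gives the most abundant gene 1 value in every library. The fits of log2 TPM change the input from counts to TPM along with the pseudocount or the scaling. All 4 ended the calls of Hsp90aa1 for both temperature comparisons, of Hspa1a for CHX at 34 °C, and of Clk4, Dyrk1a and Smg1 for the interaction, which limma on log2 scaled counts kept. Some of them ended those of Hsp90aa1 for CHX at 34 °C, of Hspa1a, Rbm3, Cd5l, G6pc and Hnrnph3 for temperature in DMSO, and of Alb and Upf3b for CHX at 38 °C. Limma on log2 scaled counts ended those of Alb with CHX at both temperatures. The replicate block ended those of Upf3b for temperature in CHX and CHX at 38 °C, of Snora69 for CHX at 34 °C and of Clk4 for the interaction. Depth limits the snoRNA genes, Hspa1a and Hspa1b, and 3 libraries per group limit the interaction. In the simulation with 200 changed genes, 2-fold interaction changes were recovered in 31.3% of cases, a share that does not carry over to the real data.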

Other observations

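The length index was chosen only after the data were seen; the tests of annotated NMD transcripts among genes that rose with CHX and of the splits were set before their results were seen.

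The authors' counts and TPM together carry an index of transcript length for each gene: log2 of count over TPM, centred in each library, follows the average transcript length their estimate assigned. Over 5191 genes with at least 5 TPM in every library and a mean of at least 20, the SD within groups had a median of 0.0252. Between 34 and 38 °C in DMSO, 141 genes were longer and 83 shorter at 38 °C, by at least 0.25 with groups that do not overlap. In CHX these numbered 129 and 78. Centring left a small offset that many listed genes share. Srsf7 and Stip1 differed by -0.048 and -0.047 in DMSO and by -0.034 and -0.033 in CHX, with groups that do not overlap. The 10% of genes without overlap by chance is therefore no guide here. The limit of 0.25 also weighs longer and shorter shifts unequally, so their balance is not read. In the same direction in both, 87 genes shifted (4.75 expected from independent sets) and 1 in opposite directions. The shifts correlated across genes, which are not independent replicates, at Pearson 0.638 and Spearman 0.552, with no library shared. Without replicate 3 of 38 °C CHX, 228 genes shifted in CHX and 99 in both.

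Several genes chosen after their values were seen show it. Cirbp, the cold-inducible RNA-binding gene, had an index of -0.67 in 34 °C DMSO and -1.01 in 38 °C DMSO, and of -0.63 and -1.04 in CHX. Tardbp moved from 0.13 to -0.46 in DMSO and from -0.10 to -0.59 in CHX. Hnrnpdl moved from 0.36 to 0.01 in DMSO, while its difference in CHX, -0.247, was under the size counted. The kinase gene Dyrk1a moved from 1.29 to 0.95 in DMSO and from 1.26 to 0.95 in CHX. Hspa8, the constitutive Hsp70, moved up, from -0.88 to -0.21 in DMSO and from -0.91 to -0.28 in CHX. Of 66 measured members of the splicing lists, 6 shifted in DMSO (9.09%, against 4.32% of all genes) and 6 in CHX. The 3 in both were Tardbp, Dyrk1a and Srrm2, a core splicing gene that was longer at 38 °C, from 1.15 to 1.41 in DMSO and from 1.47 to 1.87 in CHX. CHX shifted 94 genes at 34 °C and 182 at 38 °C.

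Other lists held calls in several comparisons, but none passed camera's test with an estimated correlation. Of 15 snoRNA host genes, 6 fell at 38 °C in DMSO (8 adjusted over the list alone; adjusted p = 0.413) and 2 rose and 1 fell in CHX (adjusted p = 0.921, median 0.04 and test downward, with a sign that turned with the scaling); with CHX 5 rose and 3 fell at 34 °C (adjusted p = 0.877), and 9 rose and 3 fell at 38 °C (adjusted p = 0.478). Snhg15 rose 4.71-fold with CHX at 34 °C and Snhg1 2.68-fold. Of the 25 ATF4 and integrated stress entries, which count Ddit3 at both of its Ensembl entries, 6 rose and 12 fell with CHX at 34 °C (median -0.32, mean 0.19, adjusted p = 0.796). At 38 °C 10 rose and 9 fell (adjusted p = 0.819). Of 24 cholesterol synthesis genes, 9 rose and 2 fell at 38 °C in DMSO (10 and 2 adjusted over the list alone; adjusted p = 0.736). Of 23 acute phase genes 13 rose and 3 fell with CHX at 38 °C (median 0.67, adjusted p = 0.707), and 1 rose and 4 fell at 38 °C in DMSO (2 and 6 adjusted over the list alone; up to 3 rose and as few as 2 fell over the scalings and the limma fit of log2(TPM + 1); adjusted p = 0.954). Of 22 fatty acid oxidation and PPAR alpha target genes, 10 rose and 7 fell at 38 °C in CHX (adjusted p = 0.91), and Pdk4, which restrains pyruvate oxidation, rose 3.76-fold, from 29.5 ± 0.907 to 104 ± 30.7 TPM. Of 31 proteasome genes, 1 rose and 14 fell at 38 °C in CHX (adjusted p = 0.771). Of 14 gluconeogenesis and urea cycle genes 8 rose and 2 fell with CHX at 38 °C (adjusted p = 0.627). Of 14 cell cycle genes, 4 rose and 1 fell at 38 °C in DMSO (adjusted p = 0.133), Mcm3 by 1.87-fold.

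The remaining lists did not pass as sets at 38 °C in DMSO, where 21% of all genes were called: of 21 cytochrome P450 genes 6 rose and 3 fell (median 0.05, mean -0.10, test upward), with Cyp3a11 up 2.05-fold, from 430 ± 74 to 918 ± 204 TPM, and of 15 fatty acid synthesis genes 4 rose and 3 fell (5 and 3 adjusted over the list alone). Of 24 immediate early genes 2 rose (0 adjusted over the list alone), of 15 p53 target genes 1 fell, and of 13 mitochondrially encoded genes 1 fell, with medians whose sign turned with the scaling. Of 18 ER chaperone genes 2 rose (0 adjusted over the list alone), of 25 ribosome biogenesis genes 5, of 39 respiratory chain genes 7, and of 80 cytosolic ribosomal protein genes 6 rose and 7 fell (1 and 3 adjusted over the list alone). Each of these had an adjusted p = 0.954. Of 3 nuclear retained noncoding genes 1 fell (2 adjusted over the list alone; adjusted p = 0.827), Neat1 by 2.31-fold, and of 9 histone genes 2 rose (3 adjusted over the list alone; adjusted p = 0.827).

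Markers of other cells were sparse. Lymphocyte and neutrophil markers had no tested gene of 14 listed, and of the red blood cell markers 1 of 6 was tested, Alas2, an enzyme of haem synthesis in red blood cell precursors, which was not called in any comparison (1.27 to 1.73 TPM). Of 4 cholangiocyte markers, 2 fell at 38 °C in CHX (3 adjusted over the list alone; adjusted p = 0.568) and 1 rose and 3 fell with CHX at 38 °C (adjusted p = 0.478). Of 4 stellate cell and fibroblast markers 1 rose and 1 fell at 38 °C in DMSO (adjusted p = 0.954), and of 9 liver endothelial cell markers 2 rose (2 and 1 adjusted over the list alone; adjusted p = 0.954).

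Stopped translation stops NMD, so genes with an annotated NMD transcript could be more frequent among genes that rose with CHX. Of 2985 protein-coding genes that rose at 34 °C, 975 (32.7%) had one, above the 29.1 to 31.8% of 10000 matched lists. That is the side set beforehand as counting for NMD of annotated transcripts as a part of the response. The lists were matched only in coarse classes of TPM and of number of annotated transcripts. Differences within a class remain, and whether they give the small excess was not tested. At 38 °C the share was 1216 of 3893 (31.2%), within 29.3 to 31.4%, which leaves NMD open there. Genes that fell had 26.3% at 34 °C (27.8 to 30.4% in matched lists) and 28.4% at 38 °C (28.6 to 30.7%).

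The 6 libraries of each pairwise comparison can be split in 10 ways, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each. With the compared groups fitted alone the real counts were 2737 and 4815 for temperature in DMSO and CHX and 8039 and 7319 for CHX at 34 and 38 °C, and the highest other split gave 0 genes in each.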
